A study of Mus musculus with 9 samples.

How the data were processed

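Messenger RNA was measured on 9 Affymetrix expression arrays, each hybridized with RNA from sorted mouse bone marrow cells. Per the labels' protocols, total RNA was extracted, 5 ng was amplified, and the cDNA was labelled with biotin. The values the authors deposited are linear intensities per probe set, a set of short probes read as 1 measurement. The submitters' processing notes name RMA, which subtracts background, normalizes between arrays by quantiles and summarizes the probes of a set, and give no version. Whether all 9 arrays were normalized together is not stated in the labels. The deposited intensities ran from 3.79 to 23176 over 45101 probe sets, and their log2 was taken before any test.

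The median intensity per array was 98.3 to 103 in the LSK group and 65.4 to 68.6 in the 6 GMP arrays, so the deposited arrays do not share 1 distribution. No depth of sequencing applies to arrays, and the number of arrays limits the precision. The median over genes of the SD between the 3 arrays of a group was 0.145 (log2) for LSK, 0.123 for WT GMP and 0.151 for NcstnKO GMP.

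Gene names came from GEO's annotation of the array. Of the 45101 probe sets, 34945 had 1 gene symbol, 932 had several, 9160 had none and 64 were control probe sets. For each gene, the probe set with the highest mean over all 9 arrays was used among those with exactly 1 symbol, which gave 18193 genes. Entrez identifiers of 18031 of these matched the RefSeq table of assembly GRCm38.p6, and 0 symbols changed through it. That table was used for names only, and no coordinates are given, because the files name no genome build.

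Before the data were examined, the groups, the comparisons, the tests, 28 gene lists (27 tested and 1 of sex-linked genes) and the rule for naming genes were fixed. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided) on 3 group means over all 9 arrays, with 6 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 18193 genes, and every adjusted p printed for a gene comes from this limma fit. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the 27 lists of a comparison. Camera with an estimated correlation and limma's fry, which asks whether a list's genes move on balance one way, were alternatives. No list passed with an estimated correlation in any of the 3 comparisons, and the smallest adjusted p was then 0.725 for NcstnKO against WT GMP, 0.188 for WT GMP against LSK and 0.325 for NcstnKO GMP against LSK. List members that are not measured by a probe set of their own under the fixed symbol were not analysed here.

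The named genes are nicastrin and the measured subunits of its complex with 7 regulators of myeloid or Notch biology, the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap (5 and 5 for NcstnKO GMP against LSK), and up to 4 members of each list with the smallest p. Sex-linked genes, predicted genes, clone names and antigen receptor segments were left out of the largest changes. Lyz2 and Gbp3 are named as the lone members against the direction of their lists, chosen after their values were seen, and Xist and Eif2s3y for the sex of the arrays. A group was taken as at background when all its arrays, or their mean, lay at or below the 95th percentile of the 27 unspiked bacterial control probe sets, a limit set after the data were examined. A fold against such a group is given as a lower bound, computed against the higher of the limit and the signal on each array.

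The arrays carry replicate numbers 1 to 3 in each group, to which the LSK titles add the letter c, and the fit has no term for them. The deviations of same-numbered LSK and WT GMP arrays from their group means correlated across genes at 0.138, 0.217 and 0.274, and each array correlated best with its own number in 3 of 3 cases. The numbers were therefore treated as a possible pairing of LSK with WT GMP, from the data and not from the labels. The check does not establish it, because deviations within a group are not independent of each other. Differently numbered WT and NcstnKO GMP arrays also correlated at up to 0.14. The fit with a replicate block called 6627 genes in WT GMP against LSK beside 6910 without it. Same-numbered NcstnKO arrays were not paired with either group by this check.

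Overlap of the first 2 comparisons was set against 100 simulations of unchanged groups sharing the WT GMP arrays, with noise independent between genes, and against 100 more, added after the data were examined, in which same-numbered LSK and WT GMP arrays shared noise. RNA quality was read as the log2 ratio of the 3 prime to the 5 prime Actb control probe set, with an exact 2-sided permutation test between groups. Xist and Y-linked transcripts were compared with the sex in the labels.

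The fit was tested on simulated data made from the real means and spreads with 200 changed genes. For NcstnKO against WT GMP it recovered 79.5% of genes changed 2-fold and 95% of genes changed 4-fold, with 8.09% and 6.4% of the calls false. For WT GMP against LSK it recovered 77% and 94%. The list test called 1 of 27 simulated lists, the 1 that had been raised, with noise independent between genes, so the simulation does not test the effect of correlated genes on list calls.

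Alternatives were a replicate block, sex from the labels as a covariate, female mice alone, a fit of the groups compared alone, leaving out the dimmest 40% of genes, the mean of all probe sets of a gene, every probe set tested alone, quantile normalization, centring on the 75th percentile, an intensity trend with robust priors, array weights, a 2-fold minimum and leaving out 1 array at a time. The following were added after the data were examined: the sex shown by the transcripts as a covariate, fits without the 4 arrays whose sex transcripts disagree with the labels or with the 5 female ones alone, a block fit of the WT groups, and, for the list tests, quantile normalization and the Actb ratio as a covariate.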

Results

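Gene expression was measured in sorted bone marrow progenitors of 6-week-old mice, in 3 groups of 3 arrays. LSK cells (lineage-negative, cKit-positive, Sca1-positive) are the fraction that holds hematopoietic stem and multipotent progenitor cells, and were taken from wild-type (WT) mice. Granulocyte-monocyte progenitors (GMP; lineage-negative, cKit-positive, Sca1-negative, CD34-positive, FcγRII/III-positive) are the committed myeloid precursors, and were taken from WT mice and from littermates lacking Ncstn (NcstnKO). Ncstn encodes nicastrin, a subunit of γ-secretase, the membrane protease that cleaves Notch receptors. Both kinds of mice carried floxed Ncstn alleles, and only the knockouts carried the Mx1-Cre transgene, which interferon switches on. All received 3 injections of polyIC, a double-stranded RNA mimic that induces interferon, at 20 µg per g from 14 days of age, and were analysed 4 weeks later. Correlations across genes between arrays of 1 group ranged from 0.988 to 0.994, those between WT and NcstnKO GMP from 0.984 to 0.990, and those between LSK and either GMP group from 0.953 to 0.976. Each group mean below rests on n = 3 arrays, and genes are not independent replicates.

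The targeted transcript was lower in every knockout array. Ncstn read 7.78 ± 0.016 (log2 intensity, SD, n = 3) in NcstnKO GMP, 9.27 ± 0.034 in WT GMP and 9.05 ± 0.074 in LSK. The knockout GMP level was 2.82-fold below WT GMP (log2 fold change −1.50, SE 0.08, limma adjusted p = 0.000287). The lowest WT GMP array lay 1.46 (log2) above the highest knockout array. A dimmer Ncstn probe set, mean 6.64, did not change (log2 fold change 0.13, adjusted p = 0.753 over all probe sets). The files do not say which probe set lies in the deleted part, and one outside it checks nothing.

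Sex transcripts did not follow the labels in 4 GMP arrays. Xist, the RNA that silences 1 X chromosome in females, read 12.3 to 12.7 in 5 arrays and 5.67 to 7.10 in the other 4. The Y-linked Eif2s3y read 3.05 to 3.54 in the former and 10.9 to 11.6 in the latter. WT GMP arrays 2 and 3 are labelled female and carried male transcripts, and NcstnKO GMP arrays 2 and 3 are labelled male and carried female transcripts. By transcripts, LSK and WT GMP each held 1 female and 2 male arrays, and all 3 NcstnKO arrays were female, so sex and genotype overlap in part.

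**Figure D1:**
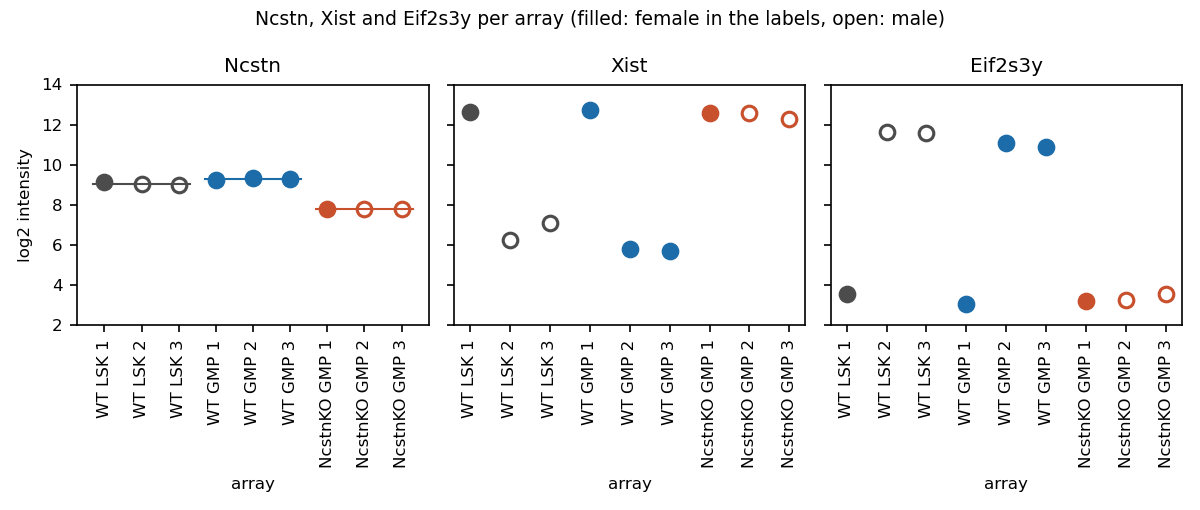
Log2 intensity of Ncstn, Xist and Eif2s3y (y axis) in each of the 9 arrays (x axis), coloured by group, filled where the label says female and open where it says male; horizontal lines in the Ncstn panel are group means. Ncstn lies at 7.78 in the NcstnKO GMP arrays and at 9.27 in WT GMP, and 4 GMP arrays show Xist and Eif2s3y levels opposite to the sex in their label.

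The comparison of NcstnKO with WT GMP asks what differs in committed myeloid progenitors that lack nicastrin. Only the knockouts carried Mx1-Cre, so an effect of the transgene cannot be told apart from that of losing nicastrin. The largest rises included Stfa3 and Stfa2l1, stefin A cysteine protease inhibitors, at log2 fold changes of 3.73 (13.2-fold, SE 0.78) and 2.28 (4.87-fold, SE 0.50), and at 2.81 (adjusted p = 0.0612) and 1.68 (adjusted p = 0.0618) without NcstnKO array 3. Il1r2, a decoy receptor for interleukin-1, rose by 2.29 (SE 0.40), and Socs3, a feedback inhibitor of STAT3 signalling, by 1.87 (SE 0.43). The largest falls included Ermap, an erythroblast membrane protein, at −2.50 (SE 0.38), Dmtn, an actin-binding protein of the red cell membrane, at −2.29 (SE 0.50), and Scd1, the stearoyl-CoA desaturase, at −2.26 (SE 0.32). In all, 1037 of 18193 genes changed (443 higher and 594 lower in the knockout), 158 of them at least 2-fold, and 4443 genes had an unadjusted p under 0.05. The split was 392 higher and 414 lower after quantile normalization, and 621 higher and 494 lower under centring on the 75th percentile.

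The other largest rises were Rab26os (2.50), Asprv1 (1.97), Wfdc17 (1.91), Ceacam10 (1.78), Slfn4 (1.68) and Ifitm6 (1.56). The other largest falls were Trim2 (−3.21, at least 6.62-fold), Tmem267 (−3.09), Tlcd4 (−2.58), Myh10 (−2.33), Slc26a1 (−2.32, at least 4.67-fold), Acsl6 (−2.28, at least 3.83-fold) and Slc38a5 (−2.26), with lower bounds where the knockout mean was at background. Tmem267 stood at −2.33 without NcstnKO array 2 (adjusted p = 0.0857) and at −4.10 without array 1. All 20 of the largest changes had adjusted p between 0.0194 and 0.0470. The other 5 Trim2 probe sets gave log2 fold changes from −1.05 to −0.02, none of which passed when each probe set was tested alone. The remaining probe sets of Scd1 (0.04), Dmtn (−0.01 and 0.19) and Myh10 (0.15) did not pass either, and those of Socs3 gave 0.95 and 1.40 without passing. In that fit the probe sets used for Tlcd4, Dmtn and Socs3 did not pass (adjusted p = 0.0578, 0.0608 and 0.0658). Of the other Tlcd4 probe sets −2.59 and −2.51 passed and −0.57 did not, and neither those of Ceacam10 (1.39 and 0.17) nor that of Acsl6 (−0.81) passed. In 5812 genes (31.95%) the 3 arrays of one group all lay above the 3 of the other, where chance gives 10%.

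As lists, erythroid and megakaryocyte transcripts tested lower in knockout GMP at the preset correlation. Of 16 erythroid markers measured, 7 fell and 0 rose (11 fell when adjusted over the list alone), with a median log2 fold change of −1.36 (camera adjusted p = 8.73e-09, and adjusted p = 0.725 with an estimated correlation). Klf1, the erythroid transcription factor, fell by 2.01 (SE 0.30), the water channel Aqp1 by 1.82 (SE 0.28), and the carbonic anhydrase Car2 by 1.24 (SE 0.18). Of 13 megakaryocyte and platelet markers, 3 fell (5 when adjusted over the list alone), namely Vwf (−1.04), Tubb1 (−0.81) and F2r (−0.64). That list had a median of −0.45 (adjusted p = 0.00187, 0.725 with an estimated correlation, and a median of −0.07 with adjusted p = 0.215 when label sex was a covariate). With transcript sex, which contradicts the labels in 4 GMP arrays, camera still called the megakaryocyte list at the preset correlation. The count of 7 erythroid markers was 4 without WT GMP array 1 or without NcstnKO array 1 or 2, and none passed limma without WT GMP array 3, with sex as a covariate or in a fit of these groups alone, where 2, 2 and 6 of all genes passed. The adjusted p of the erythroid list ran from 2.13e-14 to 0.725 over its 14 alternatives with at least 2 arrays per group (0.0824 with fry). Of the 10 splits of the 6 GMP arrays into 3 and 3, 2 gave this list as small a camera p, the real split included. The smallest other unadjusted p was 2.54e-15, against 3.23e-10 for the real split.

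Late neutrophil genes stood higher as a list at the preset correlation. Because the arrays average over all sorted cells, a change within GMP cannot be told apart from a different share of later neutrophil cells in the sort. All 18 measured members had positive log2 fold changes (median 0.51, camera adjusted p = 0.00187, adjusted p = 0.725 with an estimated correlation and a median of 0.24 with adjusted p = 0.202 when label sex was a covariate). With transcript sex, which contradicts the labels in 4 GMP arrays, camera still called the list at the preset correlation. Of the 10 splits of the 6 GMP arrays into 3 and 3, 3 gave a camera p as small as the real one, the real split included. Camp, which encodes a secondary granule antimicrobial peptide, was the 1 member that rose (0.81, SE 0.18, adjusted p = 0.0389), also when adjusted over the list alone. Chil3 (0.70, adjusted p = 0.0772), Pglyrp1 (0.54) and S100a8 (0.26) did not pass. Primary granule genes, made earlier in the lineage, had 0 of 13 past the limma test (1 at an unadjusted p under 0.05), with Mpo, the myeloperoxidase of these granules, at −0.09 (list adjusted p = 0.794). The ratio of 3 prime to 5 prime Actb signal, a measure of RNA length, was 0.899 ± 0.14 (log2, SD, n = 3) in knockout and 0.577 ± 0.111 in WT GMP (exact 2-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow).

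**Figure D2:**
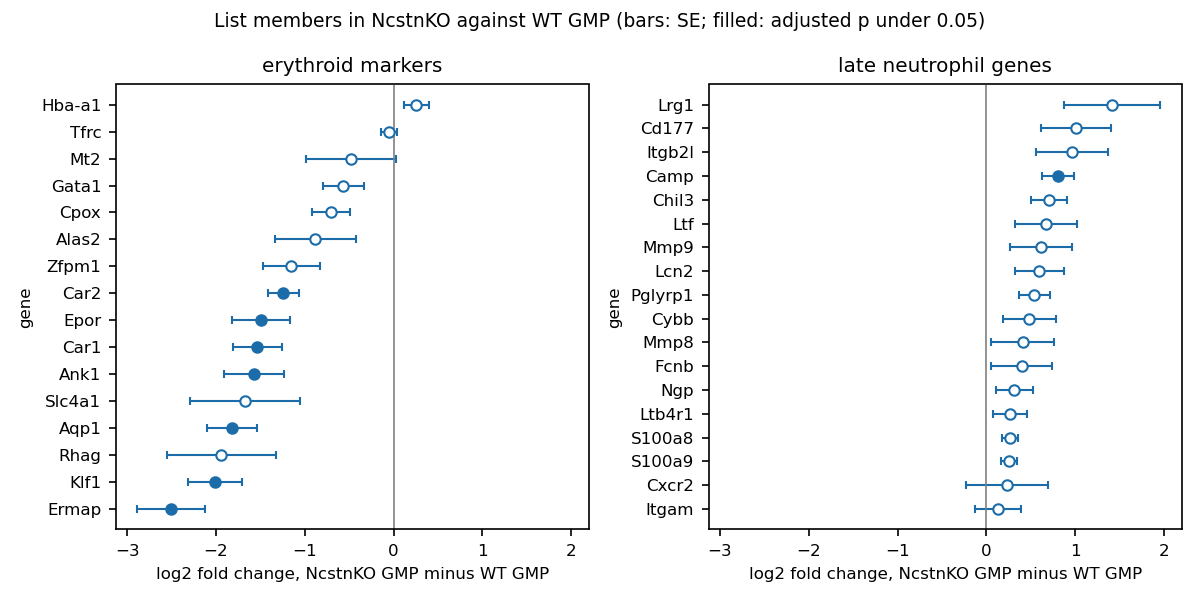
Log2 fold change of NcstnKO minus WT GMP (x axis) for each measured erythroid marker (left) and late neutrophil gene (right), with bars of 1 SE and filled points where the adjusted p is under 0.05. Of 16 erythroid markers 15 lie below 0 and 7 passed, and all 18 late neutrophil genes lie above 0 with Camp passing.

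The genes closest to nicastrin's function were tested as 3 lists. Of 5 measured γ-secretase subunits Ncstn alone fell, and Psen2 (0.08), Psenen (−0.01), Aph1a (−0.06) and Aph1b (0.18) did not pass (list adjusted p = 0.196). Of 21 Notch pathway components 1 fell, Spen (−0.65, SE 0.14), a corepressor of the Notch effector RBPJ, also when adjusted over the list alone, and Notch1 stood at −0.10, Notch2 at −0.32 and Notch4 at 0.74 without passing (4 of the list at an unadjusted p under 0.05, list adjusted p = 0.196). None of 18 Notch target genes passed the limma test over all genes (4 at an unadjusted p under 0.05), and 3 were lower when adjusted over the list alone, Igf1r (−0.56), Bcl2 (−0.54) and Gata3 (−0.47), with the list at adjusted p = 0.196. Ptcra read 3.08 to 3.30 (log2) in WT GMP, below the background limits of 4.30 to 4.39. Members at background in WT GMP cannot show a fall, so the count does not settle whether Notch output changed. Hes1, the best known Notch target, stood at 0.03 (SE 0.17, adjusted p = 0.939).

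Among cell cycle and survival genes, 1 of 24 G2/M genes fell, Prc1 (−0.42, SE 0.08), and 2 did so when adjusted over the list alone, with Mki67 (−0.36) the other. The G2/M list had a median of −0.17 (camera adjusted p = 0.00910, and 0.725 with an estimated correlation), and adjusted p from 2.31e-06 to 0.725 over its 14 alternatives with at least 2 arrays per group. The call was lost with transcript sex (median −0.03, adjusted p = 0.170) or the Actb ratio (median −0.08, adjusted p = 0.115) as a covariate, without NcstnKO array 1 (median −0.08, adjusted p = 0.0888) and without the dimmest 40% of genes (median −0.17, adjusted p = 0.214). No G1/S gene passed (0 of 24 at an unadjusted p under 0.05), with Cdc6 at −0.31 (list adjusted p = 0.315). Of 17 cyclin and checkpoint genes Cdk6 fell (−0.48) and the CDK inhibitor gene Cdkn2d rose (0.47), with 1 higher and 3 lower when adjusted over the list alone (list adjusted p = 0.359). Of 15 apoptosis regulators 2 fell, the BH3-only killer Bcl2l11 (−1.18, SE 0.15) and Casp9 (−0.55), and 3 were higher and 3 lower when adjusted over the list alone (list adjusted p = 0.196).

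Signalling lists were mixed. Of 21 JAK-STAT and RAS feedback genes Socs3 rose, and the ubiquitin ligase Cblb (−0.53) and Spred2 (−0.42) fell (2 higher and 5 lower when adjusted over the list alone). For that list the median (0.19) and the test (Down, adjusted p = 0.452) differed in sign. Of 27 interferon response genes Oas1a (0.69) and Ifi35 (0.38) rose and Usp18, which removes ISG15 and damps interferon signalling, fell (−1.35), and 3 were higher and 3 lower when adjusted over the list alone. The interferon list had a positive median (0.15), a mean just below 0 and adjusted p = 0.952. Of 17 glycolysis and hypoxia genes Bnip3 (0.72) and Ankrd37 (0.65) rose, also when adjusted over the list alone (list adjusted p = 0.790). Of 21 monocyte and macrophage genes 3 fell, the complement genes C1qa (−0.91), C1qb (−1.64) and C1qc (−1.46), and 4 did so when adjusted over the list alone, with the list at adjusted p = 0.187 (0.0215 without WT GMP array 1). Of 27 LSK and stem cell genes Thy1 rose (1.37) and Txnip fell (−0.51; 2 fell when adjusted over the list alone), with the list at adjusted p = 0.0813 (0.0338 without WT GMP array 1, 0.00418 without NcstnKO array 1, 0.00667 with transcript sex and 0.0492 with the Actb ratio as a covariate). Of 16 T and NK cell markers Prf1 fell (−0.66), also when adjusted over the list alone (list adjusted p = 0.359).

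In 13 lists no member passed limma's test over all genes, with 38 of their 221 members at an unadjusted p under 0.05. Besides the Notch target, primary granule and G1/S lists, these were myeloid transcription factors (Cebpb 0.86, Cebpa −0.14, Spi1 −0.09, Gfi1 0.26 and Irf8 −0.19), myeloid cytokine and Fc receptors (Cd34 −0.41), Hoxa genes and cofactors (Hoxa3 0.82, higher when adjusted over the list alone) and lymphoid or B cell markers (Ms4a1 −1.59). The others were mast cell, basophil and eosinophil markers (Gata2 −0.50), dendritic cell markers (Zbtb46 −1.71), stromal and endothelial markers (Col1a1 −3.27, adjusted p = 0.145, with the knockout at background), MYC and ribosome biogenesis genes (Tfdp2 −0.65), immediate early genes (Hspa1a −2.78) and inflammatory genes (Ccl5 −1.17). None of the 13 lists passed camera, with adjusted p from 0.131 to 0.952. Leaving out 1 array brought the mast cell list (0.0224, WT GMP array 1), the dendritic cell list (0.0304, WT GMP array 3) and the lymphoid list (0.000447, NcstnKO array 1) past it. With the Actb ratio as a covariate the lymphoid (median −0.63, adjusted p = 0.0492), stromal (−0.30, 0.00635), MYC (−0.14, 0.00668) and primary granule lists (0.22, 0.0463) passed. In these lists the sign of the mean or the test differed from that of the median for the myeloid transcription factors and the immediate early genes.

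The number of changed genes in this comparison depended on the arrays and covariates used. Without WT GMP array 1, 2 or 3 it was 437, 230 or 2, and without NcstnKO array 1, 2 or 3 it was 435, 477 or 145. It was 2 with sex as a covariate, whether from the labels or from the transcripts, 6 in a fit of these groups alone and 549 with the mean of all probe sets of a gene, and each of the 1037 genes kept its sign in these fits except 13 under the mean. With either sex covariate all 1037 also kept an unadjusted p under 0.05. Without 1 array no sign could change, because all 1037 genes had groups that did not overlap. The fit of these groups alone has the same fold changes. The genes were chosen by their p in these arrays, so the kept signs and p are not independent support.

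The comparison of WT GMP with WT LSK asks how the committed progenitors differ from the stem and multipotent fraction. Genes of mast cells, basophils and eosinophils and of primary granules were higher in GMP, and stem cell, lymphoid and interferon genes were higher in LSK. Of 14 mast cell, basophil and eosinophil markers 10 rose and 0 fell in GMP (median 1.96, camera adjusted p = 1.60e-10, and 0.188 with an estimated correlation), among them the eosinophil granule genes Prg2 (1.80), Prg3 (3.36) and Epx (2.78). Of 13 primary granule genes 10 rose and 1, Lyz2, fell (median 0.76, adjusted p = 1.60e-10, and 0.302 with an estimated correlation), with neutrophil elastase Elane at 1.18 (SE 0.09) and Cst7 at 1.75. Of 27 LSK and stem cell genes 23 fell and 0 rose (24 fell when adjusted over the list alone; median −2.08, adjusted p = 5.57e-08, and 0.302 with an estimated correlation), including the stem cell regulator Mecom (−3.53, SE 0.20), Procr (−3.81) and Esam (−3.98).

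In all, 6910 genes differed, 1360 higher and 5550 lower in GMP, and 2228 did so at least 2-fold (246 higher and 1982 lower). The deposited scaling matters here, because the median of all genes was −0.18 (log2) as deposited, 0.05 after quantile normalization and 0.17 after centring on the 75th percentile. The split was then 3610 higher and 2792 lower under quantile normalization and 5948 higher and 2610 lower under centring, so the numbers of higher and lower genes are relative to the scaling. The groups did not overlap in 9935 genes (54.61%, where chance gives 10%).

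The largest rises in GMP were Dmkn (3.91, 15.1-fold, SE 0.37), Il6 (3.79, at least 10.9-fold over LSK at background), the cytotoxic protease Gzmb (3.64), Prg3, Gpr85 (3.34, at least 4.48-fold), the adhesion molecule Cdh1 (3.18), Tctex1d1 (3.10), the IgE receptor genes Fcer1a (2.98) and Ms4a2 (2.87), and Scin (2.90). The largest falls were Mb21d2 (−5.95, at least 24.3-fold), Ccn3 (−5.55, at least 19.8-fold), Sema3d (−5.30, at least 24.7-fold), the germ cell helicase Ddx4 (−5.30), the transcriptional coregulator Mn1 (−4.99), the endothelial and stem cell receptor Robo4 (−4.98), Wfdc18 (−4.89), Chl1 (−4.81, at least 12.0-fold), Vnn1 (−4.57, at least 18.6-fold) and Nrk (−4.46, at least 12.0-fold). These 20 genes had adjusted p from 1.29e-05 to 0.00110.

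The 3 myeloid regulator lists held members that rose and members that fell. Of 14 myeloid transcription factors 6 rose and 2 fell (6 and 4 when adjusted over the list alone; median 0.11, mean −0.04, adjusted p = 0.0206, and 0.302 with an estimated correlation). Cebpa (0.75, SE 0.09) and Spi1 (0.76, SE 0.12), which specify the granulocyte and monocyte fates, Gfi1 (0.70) and Irf8 (0.95) rose, and Egr2 fell (−2.04). Of 17 myeloid cytokine and Fc receptors 5 rose and 5 fell (median 0.24, mean −0.04, adjusted p = 0.0478, and 0.436 with an estimated correlation), with Fcgr3, part of the GMP gate, at 1.10 and Flt3, a receptor of early progenitors, at −2.43. Of 21 monocyte and macrophage genes 7 rose and 6 fell (7 and 8 when adjusted over the list alone; median 0.16, adjusted p = 0.0206, and 0.519 with an estimated correlation), including F13a1 (0.99) and Fn1 (−1.81). After quantile normalization 6 transcription factors rose and 1 fell, 7 receptors rose and 4 fell, and 8 monocyte genes rose and 2 fell (median 0.29), and none of the 3 lists passed (adjusted p = 0.189 to 0.562). Under 75th percentile centring 7 and 1, 10 and 3, and 9 and 2 (monocyte median 0.51) did so. The monocyte call was also lost without LSK array 1 or WT GMP array 3 (adjusted p = 0.0543 and 0.0671), and the receptor call without LSK array 1 or 2 or WT GMP array 2 or 3 (adjusted p = 0.0585 to 0.0990). With the Actb ratio as a covariate the monocyte (median 0.01, adjusted p = 0.0672) and receptor calls (median 0.10, adjusted p = 0.148) were lost, and with label sex the transcription factor (median −0.01, adjusted p = 0.0514) and receptor calls (median 0.36, adjusted p = 0.0734).

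Late neutrophil, lymphoid, T and NK cell and megakaryocyte lists were lower in WT GMP than in LSK. A different share of mature cells in the LSK and GMP sorts cannot be told apart from a difference between the progenitors, because the arrays average over all sorted cells. Of 18 late neutrophil genes 14 fell in GMP and 1 rose (median −1.15, adjusted p = 0.00211, and 0.447 with an estimated correlation), with the granule proteases Mmp9 at −3.23 and Mmp8 at −2.87. Of 18 lymphoid and B cell markers 15 fell (18 when adjusted over the list alone; median −2.34, adjusted p = 0.000549, and 0.447 with an estimated correlation), including Ighm (−2.53) and the chemokine receptor Ccr9 (−4.33). Of 16 T and NK cell markers 13 fell (14 when adjusted over the list alone; median −1.53, adjusted p = 0.000757, and 0.334 with an estimated correlation), including Cd2 (−2.69) and Cd4 (−2.07). Of 13 megakaryocyte and platelet markers 10 fell (11 when adjusted over the list alone; median −0.93, adjusted p = 0.00996, and 0.436 with an estimated correlation), with platelet tubulin Tubb1 at −3.73. Of 16 erythroid markers 7 fell (9 when adjusted over the list alone), among them Klf1 (−1.45) and Epor (−1.41). The erythroid list did not pass (adjusted p = 0.112, and 0.00505 after quantile normalization), nor did dendritic cell markers (6 of 19 fell and 1 rose, adjusted p = 0.122, and 0.0150 after quantile normalization) or stromal and endothelial markers (8 of 14 fell and 1 rose, adjusted p = 0.241). Without WT GMP array 1 the erythroid list passed (adjusted p = 0.0102), as did the dendritic cell list without WT GMP array 3 (adjusted p = 0.00974). The T and NK cell call was lost without the dimmest 40% of genes, where fewer genes were tested and the median was −1.94 (adjusted p = 0.0627), and after quantile normalization 8 lymphoid and 3 erythroid markers fell, and 6 megakaryocyte markers fell and 1 rose. Under 75th percentile centring 10 lymphoid, 5 megakaryocyte, 3 erythroid and 3 dendritic cell markers fell, and 1 erythroid and 2 dendritic cell markers rose. Of the stromal and endothelial markers 5 fell and 1 rose after quantile normalization, and 6 fell and 1 rose under that centring.

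Interferon, Hoxa, Notch and cytokine feedback genes were lower in GMP. Of 27 interferon response genes 22 fell and 1, Gbp3, rose (median −1.25, adjusted p = 1.80e-06, and 0.302 with an estimated correlation), with the RNA sensor Ddx58 at −2.05 and Rtp4 at −3.76. Of 10 Hoxa genes and cofactors 7 fell (8 when adjusted over the list alone; median −1.60, adjusted p = 0.00176, and 0.302 with an estimated correlation), including Hoxa10 (−3.01) and Hoxa3 (−2.31). Of 21 Notch pathway components 12 fell (median −0.60, adjusted p = 0.0206, and 0.302 with an estimated correlation), with Notch1 at −1.33, the fringe genes Lfng (−1.59) and Mfng (−1.47), and Notch2 at −0.17 without passing. Among these components 8 fell and 1 rose after quantile normalization (median −0.20), 7 fell and 1 rose under 75th percentile centring (median −0.25), and the list did not pass without the dimmest 40% of genes (median −0.43, adjusted p = 0.266). Of 18 Notch target genes 11 fell and 1 rose (median −1.10, adjusted p = 0.0443, and 0.425 with an estimated correlation), with Gata3 at −1.99, Dtx4 at 1.94 and Hes1 at −0.11 without passing. Among these targets 9 fell and 1 rose after quantile normalization (median −0.90), and 9 fell and 4 rose under 75th percentile centring (median −0.75). Of 21 JAK-STAT and RAS feedback genes 14 fell (median −0.59, adjusted p = 0.00713, and 0.334 with an estimated correlation), including Cish (−3.41), Socs2 (−3.28) and Socs3 (−3.36), with 10 that fell after quantile normalization (median −0.38) and 8 that fell and 1 that rose under centring (median −0.24). Of 20 inflammatory genes 11 fell and 1, Il6, rose (13 fell when adjusted over the list alone, and 8 and 7 after quantile normalization and under centring; median −1.02, adjusted p = 0.0306, and 0.447 with an estimated correlation). The Notch target call was lost without LSK array 1 or WT GMP array 1 (adjusted p = 0.0861 and 0.0645) and with transcript sex as a covariate (median −1.10, adjusted p = 0.0508), and the inflammatory call without WT GMP array 3 (adjusted p = 0.0696) and with the Actb ratio as a covariate (median −1.04, adjusted p = 0.0559). Without the dimmest 40% of genes both were lost too (medians −0.11 and −1.17, adjusted p = 0.688 and 0.0928).

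Growth and metabolism lists moved upward relative to other genes. The G1/S list (median 0.11, adjusted p = 0.000507, and 0.379 with an estimated correlation) had 1 of 24 members that rose, Cdc45 (0.43), 0 when adjusted over the list alone, and 20 under 75th percentile centring. The MYC and ribosome biogenesis list (median 0.14, adjusted p = 0.000757, and 0.302 with an estimated correlation) had 3 of 21 that rose and 1 that fell, 0 either way when adjusted over the list alone, and 18 that rose under that centring, with the nucleolar gene Nolc1 at 0.30. The glycolysis and hypoxia list (median 0.09, adjusted p = 0.00710, and 0.436 with an estimated correlation) had 4 of 17 that rose, including Pfkp (0.80), and 3 that fell, including Hk1 (−0.56), with 7 and 3 when adjusted over the list alone, and 11 and 1 under that centring (median 0.44). None of these 3 lists passed after quantile normalization (adjusted p = 0.0752 to 0.154).

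The remaining lists did not pass. G2/M genes had 3 of 24 that fell, including Kif23 (−0.49; 2 when adjusted over the list alone), with a median of −0.16 that was 0.19 under 75th percentile centring, where 7 rose and 0 fell, and a test in the other direction (Up, adjusted p = 0.706). Cyclin and checkpoint genes had 7 of 17 that fell and 2 that rose (8 and 3 when adjusted over the list alone; adjusted p = 0.676; median −0.29, and 0.06 under that centring with 3 that fell and 4 that rose), with the stem cell CDK inhibitor Cdkn1c at −3.40 (at least 9.22-fold). Apoptosis regulators had 6 of 15 that fell and 2 that rose, Bid (0.84) and Bak1 (0.83), 6 and 3 when adjusted over the list alone, with a median of −0.01 (0.33 under that centring, where 8 rose and 1 fell, and −0.04 after quantile normalization, where 3 rose and 2 fell) and a test pointing up (adjusted p = 0.368). Immediate early and dissociation stress genes had 7 of 19 that fell and 1 that rose (10 and 1 when adjusted over the list alone, and 3 and 1 under either rescaling). That list had adjusted p = 0.268, 0.0155 with a replicate block, 0.0471 without WT GMP array 2, 0.00552 after quantile normalization and up to 0.792 over its 14 alternatives with at least 2 arrays per group. Of 5 γ-secretase subunits Aph1b (−1.91) and Psen2 (−0.69) fell, with the list at adjusted p = 0.894 and a median of −0.05 (0.30 under that centring). After quantile normalization 1 subunit rose and 1 fell, and under that centring 3 rose and 1 fell. Ncstn stood at 0.23 (adjusted p = 0.0423, and 0.0723 with a replicate block, from 0.000616 to 0.202 over 11 alternatives), and its direction depended on the probe set. With every probe set tested alone this one did not pass (adjusted p = 0.0560) and the dimmer one fell (−0.59, adjusted p = 0.0426), and their mean stood at −0.18 (adjusted p = 0.202).

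**Figure D3:**
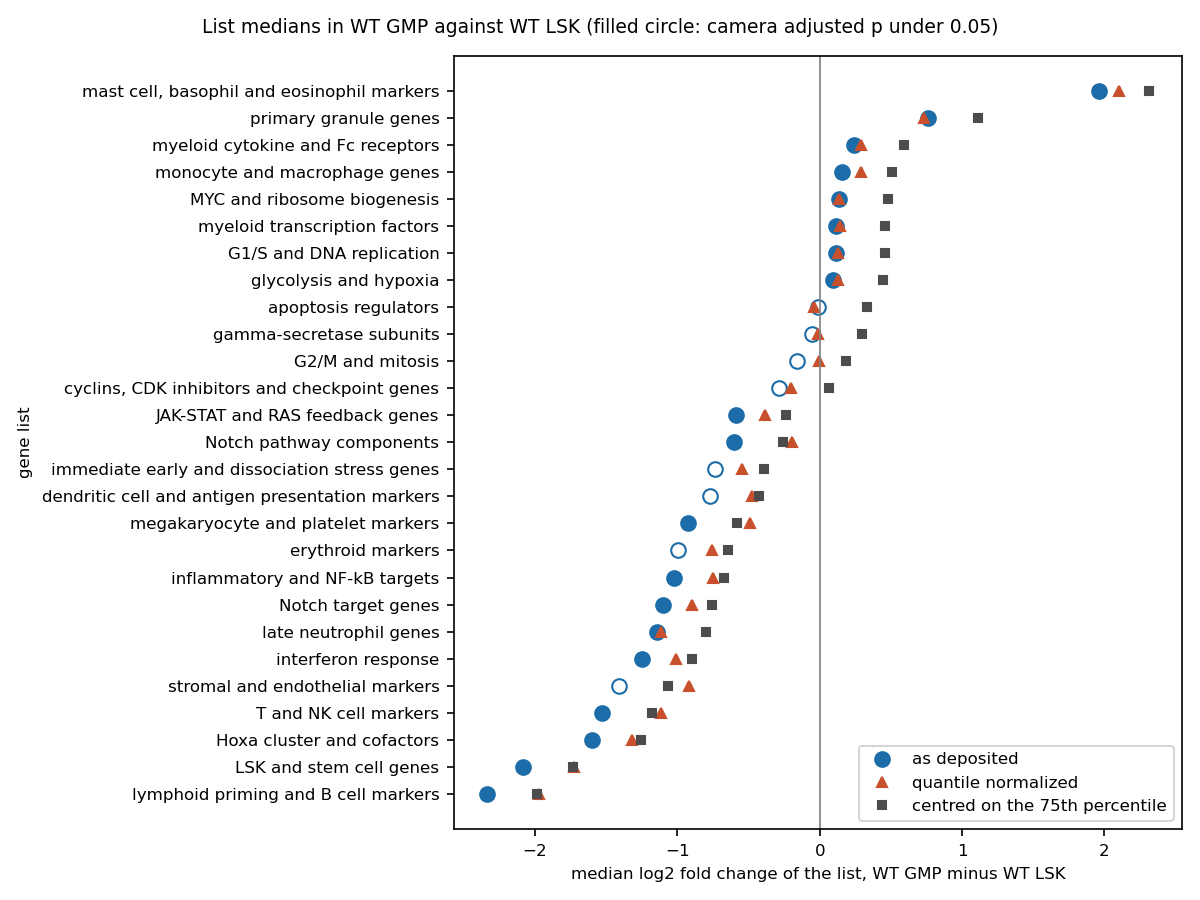
Median log2 fold change of WT GMP minus WT LSK (x axis) for each of the 27 gene lists (y axis), as deposited (circles, filled where camera's adjusted p is under 0.05), after quantile normalization (triangles) and after centring each array on its 75th percentile (squares). Mast cell, basophil and eosinophil markers lie highest at 1.96 as deposited and lymphoid and B cell markers lowest at −2.34, and the rescaled medians lie to the right in most lists, with the G2/M, cyclin, apoptosis and γ-secretase medians crossing 0 under centring.

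The comparison of NcstnKO GMP with WT LSK sets the knockout progenitors against the same LSK arrays as WT GMP, with genotype and population differing together. The deposited LSK and GMP arrays do not share a distribution, so these values too are relative to the scaling. Ncstn was 2.41-fold lower in knockout GMP than in LSK (log2 fold change −1.27, SE 0.08). Cebpa (0.62), Spi1 (0.67) and Gfi1 (0.96) rose, Notch1 (−1.43) fell, and Irf8 rose by 0.76 (adjusted p = 0.0468). The Irf8 call was lost with a replicate block (adjusted p = 0.0640), and its adjusted p ran from 0.00860 to 0.149 over 11 alternatives. The largest rises were Dmkn (5.35, 40.8-fold), Tctex1d1 (3.97), Fcer1a (3.80), Gpr85 (3.64, at least 5.49-fold) and Il6 (3.53, at least 9.14-fold), and the largest falls were Ddx4 (−6.60, at least 45.8-fold), Mb21d2 (−6.04, at least 22.7-fold), Sema3d (−5.96, at least 23.1-fold), Gucy1a1 (−5.41) and Robo4 (−5.40, at least 33.9-fold). The other Gucy1a1 probe sets gave −2.65 and −3.00. In all 8523 genes differed, 2648 higher and 5875 lower, with 5441 higher and 3805 lower after quantile normalization and 7959 higher and 3205 lower under 75th percentile centring. The median of all genes moved from −0.12 to 0.09 and 0.26 with these scalings.

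In the same comparison 15 of 27 lists passed, 5 up and 10 down, and none did with an estimated correlation (smallest adjusted p = 0.325). Erythroid markers had 13 of 16 that fell (14 when adjusted over the list alone; median −2.51, adjusted p = 0.000483, and 0.413 with an estimated correlation). LSK and stem cell genes had 24 of 27 that fell (median −2.58, adjusted p = 1.17e-07), interferon response genes 22 of 27 that fell and 2 that rose (adjusted p = 5.03e-05), and Notch pathway components 14 of 21 that fell, 10 after quantile normalization (adjusted p = 0.00188), each at adjusted p = 0.325 with an estimated correlation. Mast cell, basophil and eosinophil markers had 10 of 14 that rose (median 1.83, adjusted p = 1.35e-05) and primary granule genes 10 of 13 that rose and 1 that fell (adjusted p = 3.52e-07), also at 0.325 with an estimated correlation. Late neutrophil genes had 9 of 18 that fell and 1 that rose, and the list did not pass (median −0.80, adjusted p = 0.120), but passed after quantile normalization (median −0.42, adjusted p = 0.00917). The monocyte and macrophage (median 0.01, mean −0.17) and myeloid receptor lists (median 0.19, mean −0.11) had medians and means of opposite sign, and neither passed.

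The overlap of the first 2 comparisons asks whether the knockout changes run along the difference between LSK and GMP. Of the genes called in NcstnKO against WT GMP, 529 were also called in WT GMP against LSK. There were 350 genes lower in both, among them Klf1, Vwf and Tubb1, where independent lists would share 181, and 42 higher in both, where they would share 33.1. There were 125 genes higher in the knockout and lower in WT GMP than LSK (135 for independent lists), among them Socs3 and Camp, and 12 lower in the knockout and higher in WT GMP (44.4). These counts by direction rest on the deposited scaling and were not recomputed under the others. In WT GMP against LSK those gave 3610 higher and 2792 lower genes (quantile normalization), and 5948 and 2610 (75th percentile centring). Across genes the fold changes correlated at 0.106, against −0.498 (range −0.539 to −0.453) in 100 simulations of unchanged groups that share the WT GMP arrays, with independent noise. With the noise of same-numbered LSK and WT GMP arrays correlated at 0.21, as measured, the simulated value was −0.442 (range −0.483 to −0.394). The simulated LSK and WT GMP groups did not differ, while 6910 genes differed in the data. Real differences widen the spread of the fold changes, so neither simulated correlation is a baseline for 0.106. The covariance is not divided by that spread. The covariance was 0.0271 against −0.0225 with independent noise, a difference of 0.0495, and −0.0177 with shared noise. The 3 shared arrays were too few to be split, and the count of 529 was 212, 127 or 1 without WT GMP array 1, 2 or 3 and 1 with sex as a covariate.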

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

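Among the tests below, those of exchanged arrays, of exchanged sex entries and of the spiked controls were chosen after the result was seen.

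In 4 arrays Xist and Y-linked transcripts disagreed with the sex in the labels, which stood out because sex is a label no comparison used. An exchange of WT and NcstnKO arrays is argued against by Ncstn, whose lowest WT GMP array lay 1.458 (log2) above the highest NcstnKO array, where exchanged arrays would lie in the other group's range. Giving each WT GMP array the sex entry of the same-numbered NcstnKO array, and the reverse, made 9 of 9 arrays match their transcripts. A candidate explanation is therefore that the sex entries of the GMP groups were exchanged, found and tested on the same data. No biological explanation was tested.

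Erythroid markers were lower in NcstnKO GMP, with a list median of −1.36 (log2). A difference in sex between the groups and RNA length or labelling were examined as causes. The list median was −1.352 (camera adjusted p = 3.22e-10) with transcript sex as a covariate, and −1.514 (adjusted p = 2.40e-09) with the Actb ratio. Neither covariate removed the lower median, but both p rest on the preset correlation. Without covariates the adjusted p was 0.725 at the list's estimated correlation of 0.541, and 0.0824 with fry. The Actb ratios of the GMP groups did not overlap, so that fit cannot compare them at an equal ratio. Neither cause is excluded by these fits. With transcript sex no single member passed, although Klf1 stood at −2.05 beside −2.01 without it, because all NcstnKO arrays carry female transcripts and the covariate leaves a less precise difference. Of 11 genes taken as erythroid-restricted, which was not tested here, 10 were lower, 6 of which passed, and the other, Hba-a1, was at background in WT GMP. The 10 lower genes had SDs of 0.431 to 0.995 between WT GMP arrays, beside a median SD of 0.123 over all genes. Fewer erythroid-lineage cells in the NcstnKO sort may account for the pattern and stay open, because these genes restate the pattern and the arrays hold no count of cells. A change of these genes within GMP, the biological explanation that the genotype gives, cannot be told apart from this, because the arrays average over all sorted cells.

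More genes were lower than higher in WT GMP against WT LSK, with a median of −0.178 over all genes. Spiked controls, which do not come from the cells, shifted by a median of −0.08801 (SE 0.0291, 18 probe sets), and the dim unspiked controls by −0.0786 (SE 0.0453, 27 probe sets), so the controls show no dependence of the shift on brightness. The spiked shift differs from that of all genes by narrowly more than the bound of 3 SE set for excluding the scaling. That bound was set aside after the value was seen, because several control probe sets measure each spiked transcript and are not independent, and because the 4883 genes as bright as them shifted by −0.0457 and not by −0.178. Every LSK array had a higher median intensity than every GMP array. Quantile normalization, a step of the RMA named in the processing notes, gives arrays processed together nearly the same distribution. The intensities therefore argue against a joint normalization of the LSK and GMP arrays, so that scaling and population differ together. A lower level of many transcripts in GMP cannot be told apart from the scaling with these controls.

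The bioB and bioC spike-in controls, which no comparison used, read 11.07 ± 0.074 in NcstnKO and 10.76 ± 0.016 in WT GMP (log2, SD, n = 3), a difference of 0.3173 (exact 2-sided permutation p = 0.1, the smallest possible). The 18S rRNA 5 prime control probe set, also outside the comparisons, read 10.82 ± 0.291 in WT GMP and 8.481 ± 0.914 in LSK, a difference of 2.336 (exact 2-sided permutation p = 0.1). Of 10092 probe sets without a single gene name, left out of the gene tests, 82 passed limma in NcstnKO against WT GMP, 41 of them higher.

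The 6 arrays of a comparison allow 10 splits into 3 and 3, too few for a share under 0.05. For NcstnKO against WT GMP the real split called 1037 genes and the highest other 1, for WT GMP against LSK 6910 and 1, and for NcstnKO GMP against LSK 8523 and 0, so that 1 split of 10, the real one, reached the count each time. For the gene lists the real splits called 4, 19 and 15, the highest others 9, 14 and 16, and 8, 1 and 2 of the 10 splits called as many. In NcstnKO against WT GMP, splits with a camera p as small as the real one, itself included, were 3 for late neutrophil and 3 for G2/M genes. They were 2 each for erythroid and megakaryocyte markers, so the splits leave chance open for these 4 list calls.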

How the results depend on the processing

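Sex by transcripts, the fits without the 4 arrays of disagreeing sex or with the 5 female ones, the block fit of the WT groups, and, for lists, quantile normalization and the Actb covariate were chosen after the result was seen.

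In NcstnKO against WT GMP the 1037 genes became 370 with a replicate block, 2 with sex in the labels or by transcripts as a covariate, 1 with females by the labels only, 6 with only the 2 groups compared, 549 with the mean of probe sets, 158 at a 2-fold minimum and 1 without the 4 arrays of disagreeing sex. With the 5 arrays of female transcripts limma called 0 genes (1669 at an unadjusted p under 0.05). The last 2 fits leave 1 WT GMP array, females by the labels leave 1 NcstnKO and 1 LSK array, the fit without the 4 leaves 1 NcstnKO array too, and the lone array is assumed to vary like the other groups. Leaving out 1 array gave 2 to 477, the lowest without WT GMP array 3. The 790 to 1550 genes of the other settings were within 1.5 times. The 6910 genes of WT GMP against LSK became 3813 with females only, 4174 without the dimmest 40% (fewer genes tested), 15710 with every probe set on its own (more tested), 2228 at a 2-fold minimum and 2383 without the 4 arrays. Leaving out 1 array gave 5374 to 6098. The 8523 of NcstnKO GMP against LSK became 3789, 19575, 2760 and 3593 with females only, every probe set, a 2-fold minimum and without the 4 arrays, and 7379 to 7760 without 1 array. The share of higher genes in WT GMP against LSK was 19.7% as deposited, 56.4% after quantile normalization and 69.5% after 75th percentile centring. It was 31.1%, 58.9% and 71.3% in NcstnKO GMP against LSK, and 42.7%, 48.6% and 55.7% in NcstnKO against WT GMP. Lists past camera in NcstnKO against WT GMP were 4, and 0 with an estimated correlation, 2 with label sex, 8 with the Actb ratio and 4 to 7 without 1 array, 7 without WT GMP array 1. Fry passed 1 list, none of the 4 but the γ-secretase subunits (adjusted p = 0.00202), of which only Ncstn, the deleted gene, fell. With an estimated correlation the lists past camera were 0 instead of 19 and 15 in the other comparisons. The overlap of 529 genes was 1 with either sex covariate and 1 to 212 without 1 WT GMP array. The Gapdh ratio gave 0.127 and 0.01438 where Actb gave 0.322 and −0.171. Reversed were the lymphoid list in NcstnKO against WT GMP, 0.918 without the 4 arrays, with 1 array on each side and the spread taken from LSK alone (−0.33 otherwise), and in WT GMP against LSK the myeloid receptor list, whose median of 0.2407 fry reads as down, the Notch target list, −0.1078 without the dimmest 40% and tested as up, and Ncstn, −0.1833 with the mean of probe sets. Hes1 in NcstnKO GMP against LSK was 0.4799 after quantile normalization (−0.08 otherwise). A replicate block changed the calls of Ncstn, Nop16 and Gins1 and of the immediate early list in WT GMP against LSK and no other named gene or list there. In the NcstnKO comparisons, where same-numbered arrays correlated at −0.0998 to 0.0439, it changed 27 named genes and the stem cell list (adjusted p = 0.0261) against WT GMP, and Irf8 and 3 lists against LSK. The sex covariates each ended the calls of 46 named genes in NcstnKO against WT GMP. Where no construction is named, the cause was not tested. Signal at background limits folds of dim genes to lower bounds.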

Other observations

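Several gene groups of NcstnKO GMP against WT LSK were not described above. Lymphoid and B cell markers had 15 of 18 that fell (median −2.72, adjusted p = 0.000483, and 0.458 with an estimated correlation), and T and NK cell markers 13 of 16 (median −1.49, adjusted p = 0.000822, and 0.325 with an estimated correlation). Megakaryocyte and platelet markers had 11 of 13 that fell (adjusted p = 0.00184, and 0.361 with an estimated correlation), with platelet tubulin Tubb1 at −4.55. Hoxa genes and cofactors had 7 of 10 that fell (adjusted p = 0.00785), Notch target genes 12 of 18 that fell and 1 that rose (adjusted p = 0.0144), and JAK-STAT and RAS feedback genes 13 of 21 that fell (adjusted p = 0.0112), each at adjusted p = 0.325 with an estimated correlation. Myeloid transcription factors had 7 of 14 that rose and 1 that fell (adjusted p = 0.0441, and 0.325 with an estimated correlation). Glycolysis and hypoxia genes had 6 of 17 that rose and 2 that fell (adjusted p = 0.0145, and 0.458 with an estimated correlation), and the G1/S list 3 of 24 that rose (adjusted p = 0.0384, and 0.524 with an estimated correlation). The myeloid transcription factor call was lost without LSK array 2 or NcstnKO array 1 or 2 (adjusted p = 0.0606 to 0.0814), and the G1/S call without LSK array 1 or NcstnKO array 2 (adjusted p = 0.130 and 0.0583). With the Actb ratio as a covariate both calls were lost (adjusted p = 0.0556 and 0.0925). A replicate block also ended the transcription factor call (adjusted p = 0.0698). After quantile normalization the calls of the G1/S, glycolysis and myeloid transcription factor lists were lost (adjusted p = 0.355, 0.0989 and 0.265), and under 75th percentile centring 20 of 24 G1/S genes rose and 12 of 17 glycolysis genes rose and 1 fell. Megakaryocyte markers had 7 that fell and 1 that rose after quantile normalization. Without the dimmest 40% of genes those of the Notch target and T and NK cell lists were lost (medians −0.50 and −1.47, adjusted p = 0.581 and 0.102). All medians printed here are relative to a median of −0.12 over all genes.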
